A study of Mus musculus with 78 samples.

How the data were processed

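Endothelium-enriched RNA from the left (LCA) and right (RCA) common carotid artery of 39 mice was profiled on 78 Affymetrix mouse expression arrays, 1 array per artery. Per the labels' protocols, partial ligation of the LCA was performed on every mouse, RNA was flushed from each artery with Qiazol and isolated with a miRNeasy kit, and biotin-labelled cRNA was hybridised. The values used here are the authors' deposited log2 expression values, normalized with RMA per the submitters' processing notes; the RMA software, its version and the chip definition are not given in the sources used here. Values ranged from 1.79 to 13.235, and array medians from 4.59 to 4.77, so no further normalization was applied in the main results. RMA sets all arrays to a common distribution, so that a shift of most genes in the same direction would not be seen, and low signals are compressed towards the background. The number of arrays limits the precision; there is no count depth.

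Groups were taken from the labels: treatment (vehicle or atorvastatin at 10 mg/kg/day), artery and time (12 h, 24 h, 48 h or 2 weeks), 16 groups of 5 arrays, except 4 for each artery under atorvastatin at 48 h. The replicate number in each title joined the LCA and RCA of a mouse. The labels mention 4 batches of extraction and profiling without saying which sample was in which, so batch could be neither tested nor separated from treatment or time. The leading number of the title code, shared by both arteries of a mouse, served as an alternative block.

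Of 45118 probe sets, 81 controls were left out, 28898 carried 1 gene symbol in the platform annotation, 551 several and 15588 none; names were taken only from probe sets with 1 symbol. A gene with more than 1 probe set (7180 of 17097 genes) was represented by the probe set with the highest mean, and a gene was tested when it lay above the array median (50th percentile) on at least 4 arrays, which left 11344 genes. Gene symbols identify each result; positions in the genome were not used here.

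For each mouse the LCA minus RCA difference was computed, and limma 3.58.1 (statmod 1.5.0, R 4.3.3) was fitted to these differences over all 8 mouse groups with a shared variance estimate. LCA values, RCA values and the mean of both arteries were fitted in the same way for comparisons between mice. The comparisons were LCA against RCA at each time in each treatment, the change over time (F test, and pairs of times from the same fits), atorvastatin against vehicle in each artery, in the mean over the 4 times and in the mean of both arteries, and the effect of atorvastatin on the LCA minus RCA difference (the interaction of treatment and artery). P-values were adjusted by Benjamini-Hochberg over the tested genes, and genes with an adjusted p under 0.05 were counted. Samples of a group came from separate mice.

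Before the data were examined, 33 gene lists were fixed, 18 for pathways and 15 for cell types, with 449 genes, of which 396 had a named probe set and 345 were tested. The pathway lists were laminar flow-associated genes, endothelial inflammation and adhesion, TGF-beta and mesenchymal transition, Notch and arterial identity, YAP/TAZ targets, cell cycle, cholesterol synthesis and uptake, unfolded protein response, interferon response, antigen presentation, immediate early genes, extracellular matrix, NRF2 and oxidative stress, angiogenic tip cell, coagulation and fibrinolysis, hypoxia and glycolysis, and DNA methylation enzymes. The cell lists were endothelial, lymphatic endothelial, smooth muscle, fibroblast, adipocyte, Schwann cell, skeletal muscle, macrophage, neutrophil, T cell, B cell, dendritic cell, platelet, erythroid and thyroid. Lists with at least 3 tested genes (29) were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, adjusting over the lists of a comparison. The circadian clock genes were a further list, chosen after the data were seen.

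The comparisons, tests, alternatives and the rule for naming genes were also fixed before the data were examined. For LCA against RCA in vehicle-treated mice the rule named the 8 largest rises and 8 largest falls among genes past the threshold that moved the same way in every mouse; for other comparisons it named 5 and 5, or the 10 genes of smallest p for F tests. It also named up to 4 called members of each list, and in every comparison Klf2, Klf4, Nos3, Vcam1, Icam1, Klk10, Hmgcs1, Sqle and Insig1. Some genes of this rule and 1 pathway list are not reported here. Smaller ones were left out where a comparison would have had over 30 names, and predicted genes were not named.

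The fits were tested on simulated data with 200 changed genes in each of 5 runs over 11344 genes. The simulated values were normal and independent between genes and mice, so the rates need not hold for correlated genes or outlying mice. For LCA against RCA in vehicle-treated mice at 48 h, 71.8% of changes of log2 1 and 20.2% of changes of 0.5 were recovered, with 4.6% false calls. For atorvastatin against vehicle in the LCA at 48 h these were 59.4%, 14.6% and 5.1%, and for the mean of the 4 times in the LCA 97.2%, 71.2% and 4.5%. The pairing of arteries rests on the labels, which give both arteries of a mouse the same number. As a check, the deviations of an LCA and the RCA of the same mouse from their group means had a median correlation across genes of 0.09 (range -0.34 to 0.51), 19 of 39 were over 0.1, and 18 of 39 LCA arrays correlated best with the RCA of their own mouse.

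RNA quality was read from the 3' minus 5' difference of the Gapdh control probe sets (log2), and the same difference was computed for the b-actin control probe sets. Alternatives were a fit to the groups compared alone, a fit without pairing of the arteries, pairing as a random effect, no signal filter, a stricter filter (75th percentile), the mean of all probe sets of a gene, limma with trend and robust options, quantile normalization once more, the title code number as a block, and leaving out each mouse in turn. Exact permutation tests were used for list means of 5 against 5 mice. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.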

Results

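Endothelium-enriched RNA was flushed from the left and right common carotid arteries (LCA and RCA) of 39 mice and measured on 78 expression arrays, 1 per artery. Partial ligation of the LCA, an operation that closes most of the artery's downstream branches and leaves it with low and disturbed flow, had been performed on every mouse, and the RCA of the same mouse served as its control. Mice received atorvastatin, a cholesterol-lowering drug of the statin class, at 10 mg/kg/day or vehicle from 2 days before surgery, and arteries were taken at 12 h, 24 h, 48 h or 2 weeks. Each of the 16 groups held 5 arteries, except atorvastatin at 48 h with 4 LCA and 4 RCA. The number of arrays limits the precision, and the array medians lay between 4.59 and 4.77 on the log2 scale. Changes below are log2 differences between the arteries of each mouse (LCA minus RCA), or between groups of mice, over 11344 genes. Each is given with the standard error (SE) of the limma fit and Benjamini-Hochberg adjusted p. Gene lists were tested with camera at a preset correlation, and where a call was lost with a correlation estimated from the data, that p is given too.

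At 12 h after ligation in vehicle-treated mice, the genes with the largest rise in the LCA over the RCA were Angpt2, which encodes the vessel-destabilising ligand angiopoietin-2 (3.15, SE 0.59, adjusted p = 0.00152), Depp1 (3.02, SE 0.50) and the stress-response gene Gadd45a (2.40, SE 0.44). Further rises were Frzb (2.29), Ccn2, the connective tissue growth factor (2.25, SE 0.35), Cdo1 (2.21), Klf15 (2.13) and Slc10a6 (2.08). Tcf23 (-2.75, SE 0.24, adjusted p = 1.3e-09), Nrm (-2.73), the flow-responsive transcription factor gene Klf2 (-2.39, SE 0.20, adjusted p = 9.53e-10), Nxnl2 (-2.18) and the elastin gene Eln (-1.99) had the largest falls. They were followed by Col6a3 (-1.97), the Notch ligand gene Dll1 (-1.78) and the kallikrein gene Klk10 (-1.74, SE 0.30). Only genes that moved the same way in 5 of 5 mice were ranked here. Among genes reported in every comparison, Klf4 (-0.95, adjusted p = 0.15) and Nos3, the endothelial nitric oxide synthase (-0.65, adjusted p = 0.058), did not pass the test at this time. Nor did the adhesion molecules Vcam1 (0.50, adjusted p = 0.22) and Icam1 (0.40, adjusted p = 0.11).

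Of 15 laminar flow-associated genes measured at 12 h, 3 fell (Klf2, Klk10 and Timp3) and 0 rose, with 8 lower when adjusted over the list alone; the list median was -0.44 (camera adjusted p = 4.76e-10). Of 17 genes for endothelial inflammation and adhesion, 4 rose: Edn1, encoding endothelin-1 (1.89), Tnfaip3, a feedback inhibitor of NF-kB (1.28), the chemokine gene Cxcl1 (1.11) and Bmp4 (0.67). With adjustment over the list alone 8 rose, and the list median was 0.42 (camera adjusted p = 1.79e-07). The coagulation list had 1 of 10 members lower, 3 when adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.0376). These 3 lists were called with an estimated correlation as well (adjusted p = 0.0174, 0.0265 and 0.0493). No other list was called at 12 h. Single members of such lists rose, among them Gja4 (1.02) and Hey1 (0.77) of the Notch and arterial list and Ccn2 and Crim1 (0.93) of the YAP/TAZ list. Cdkn1a of the cell cycle list fell (-1.29). In all, 271 genes differed between the arteries, 149 higher and 122 lower in the LCA. Quantile normalisation applied once more gave 112 higher and 138 lower, and a fit to these 5 mice alone called 72. Without mouse 1, 2, 3 or 5 the count was 167, 147, 147 and 175. The calls of Timp3, Cdkn1a and Hey1 were lost without each of at least 4 mice in turn, that of Cxcl1 without mouse 2 or 3 and that of Slc10a6 without mouse 3 or 5.

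By 24 h in vehicle-treated mice, 1620 genes differed, 816 higher and 804 lower in the LCA, and 1047, 898 and 920 without mouse 2, 3 or 5. Depp1 (3.51), Gadd45a (3.19), Ccn2 (2.38), the pyruvate dehydrogenase kinase gene Pdk4 (2.36, SE 0.24, adjusted p = 2.7e-08), and E-selectin (Sele, 2.36, SE 0.66, adjusted p = 0.014) led the rises, followed by Sox4 (2.33), Dzank1 (2.31) and Abcb1b (2.29). The leading falls were Nrm (-3.54), Klk10 (-3.20, SE 0.30, adjusted p = 3.4e-09), Tcf23 (-3.19), Klf2 (-3.01, SE 0.20, adjusted p = 1.1e-12) and the BMP target Id1 (-2.72). Zbtb7c (-2.69), Mob2 (-2.68) and Spry4 (-2.67) also fell. The ranking was again limited to genes that moved the same way in 5 of 5 mice. Nos3 (-1.32, SE 0.19) and Klf4 (-1.41, SE 0.33) were past the threshold at 24 h, as was Icam1 (0.42, SE 0.13, adjusted p = 0.027), while Vcam1 was not (0.30, adjusted p = 0.32). Tested directly with limma, the difference between the arteries changed from 12 h to 24 h for 0 genes. The Icam1 call was lost without mouse 2, 3, 4 or 5 (adjusted p = 0.0598, 0.0609, 0.104 and 0.0944), and that of Sele without mouse 4 (1.91, adjusted p = 0.0818) or 5 (2.22, adjusted p = 0.0582). Insig1, a sensor of sterol supply, rose by 0.99 (SE 0.17), and Sqle did not pass (0.20, adjusted p = 0.72).

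At this time 8 of 15 laminar flow-associated genes fell (9 fell and 1 rose when adjusted over the list alone; median -0.82, camera adjusted p = 1.32e-08), including Gch1, which makes the cofactor of nitric oxide synthase (-1.34). That call held with an estimated correlation (adjusted p = 0.0377). The inflammation list had 7 of 17 members higher, 8 over the list alone, with Cxcl2 at 2.13 and Edn1 at 2.01 (median 0.42, camera adjusted p = 2.25e-05), and was not called with an estimated correlation (adjusted p = 0.105). Lists with members on both sides were not called. In Notch and arterial identity, for example, 3 rose, including Gja4 (1.19), and 3 fell, including Gja5 (-1.96) and Jag1 (-1.10). Of 14 endothelial markers 3 fell, including Icam2 (-1.83) and Cldn5 (-1.14), and 1 rose, and the list was not called (camera adjusted p = 0.274). The call of Cldn5 was lost without mouse 1, 2, 3 or 5. The 3' to 5' ratio of the Gapdh control probe sets, a measure of RNA degradation, was 4.98 ± 0.47 (log2, SD, n = 5) in the LCA and 4.04 ± 0.24 in the RCA at 24 h. At 12 h it had been 4.82 ± 0.30 and 4.74 ± 0.31. The arteries thus differed in this ratio at 24 h and hardly at 12 h, so that degradation was not separated from ligation in the 24 h calls. Its part in the larger count at 24 h was not tested. For the b-actin control probe sets the ratio was -0.034 ± 0.197 in the LCA and -0.275 ± 0.185 in the RCA at 24 h. At 12 h the b-actin values were 0.185 ± 0.342 and -0.083 ± 0.378.

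**Figure D1:**
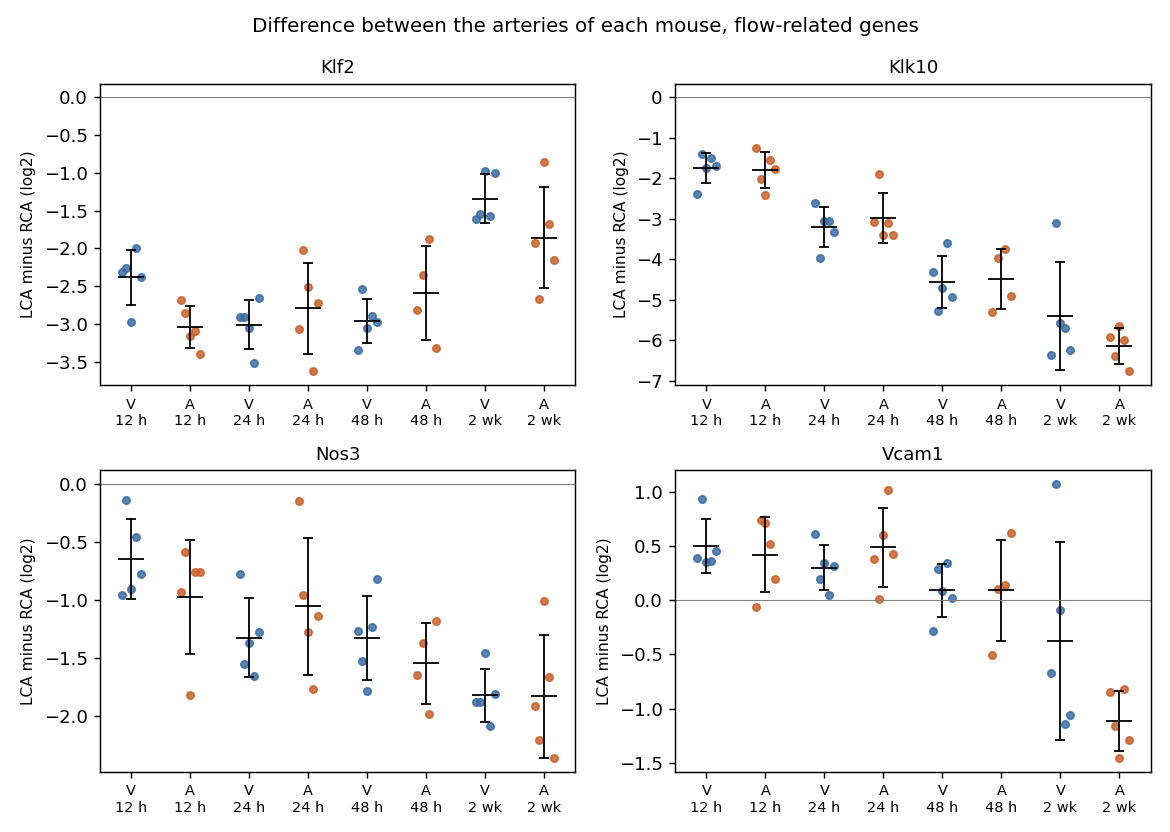
LCA minus RCA difference (log2) of Klf2, Klk10, Nos3 and Vcam1 for each mouse (points; blue vehicle, orange atorvastatin) at 12 h, 24 h, 48 h and 2 weeks, with the mean and SD of each group as bars. In vehicle-treated mice the Klk10 difference was -1.74 at 12 h and -5.39 at 2 weeks, whereas Klf2 was lowest at 24 h (-3.01).

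In the LCA of vehicle-treated mice at 48 h, genes of neutrophils, the cell cycle and angiogenic tip cells were high. Among genes that moved the same way in 5 of 5 mice, Adam12 (5.25, SE 1.04) and the interleukin gene Il1b (5.21, SE 0.63, adjusted p = 3.1e-07) rose most. They were followed by Slfn1 (5.12) and Chil3 (5.04). Next came Angpt2 (4.76, SE 0.59), Slfn4 (4.74), the leukocyte gene Coro1a (4.48) and Igfbp3 (4.46). Klk10 (-4.56, SE 0.30, adjusted p = 4.04e-13), Ptprr (-4.09, SE 0.40), Fndc1 (-3.86), Vwc2 (-3.60), Spock2 (-3.41), Fam107a (-3.39), Clic5 (-3.32) and Col4a3 (-3.24) fell most under the same restriction. Klf2 (-2.96), Klf4 (-2.61) and Nos3 (-1.32) were lower, and Vcam1 (0.09, adjusted p = 0.75) and Icam1 (0.29, adjusted p = 0.082) were not called. The cholesterol synthesis gene Sqle rose by 1.53 (SE 0.29, adjusted p = 0.00013).

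Cell cycle genes rose as a group at 48 h, with 21 of 25 higher (23 over the list alone), for example Rrm2 (2.80, SE 0.58), Mcm5 (2.56), Birc5 (2.27) and Cdk1 (2.21). The median of that list was 1.77 (camera adjusted p = 5.45e-09; adjusted p = 0.387 with an estimated correlation). Neutrophil markers rose in 6 of 7, with the calprotectin genes S100a8 at 4.99 (SE 0.75) and S100a9 at 4.52 (SE 0.79) and the receptor gene Cxcr2 at 3.71. Their median was 3.31 (camera adjusted p = 0.000322; adjusted p = 0.375 with an estimated correlation). Macrophage markers rose in 7 of 12, 9 over the list alone, including Fcgr1 (3.22) and Lyz2 (2.19). The macrophage median was 1.44, at camera adjusted p = 0.000517 (adjusted p = 0.387 with an estimated correlation). Antigen presentation genes rose in 7 of 11 and fell in 2, with Cd74 at 2.62 and H2-Ab1 at 2.58 (camera adjusted p = 0.0312; adjusted p = 0.447 with an estimated correlation). Angiogenic tip cell genes, which mark sprouting endothelium, had 8 of 12 higher and 1 lower. Esm1 rose by 5.55 (SE 0.80) and Pdgfb by 2.39 (list camera adjusted p = 0.00318; adjusted p = 0.375 with an estimated correlation). Hypoxia and glycolysis genes rose in 8 of 16, among them Hk2 (1.64), at camera adjusted p = 0.0231 (adjusted p = 0.387 with an estimated correlation).

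The unfolded protein response list had 12 of 19 members higher and 2 lower at 48 h, led by Asns (3.16, SE 0.49) and Sdf2l1 (1.64), with camera adjusted p = 0.0161 (adjusted p = 0.447 with an estimated correlation). Interferon-response genes went down, with 6 of 15 lower, for example Ifit3 (-1.68, SE 0.33) and Ifit1 (-1.65, SE 0.30). Their camera adjusted p was 0.0138 (adjusted p = 0.447 with an estimated correlation). Fibroblast markers fell in 5 of 9, including Mfap5 (-2.13), at camera adjusted p = 0.0192 (adjusted p = 0.495 with an estimated correlation). Laminar flow-associated genes fell in 12 of 15 (13 over the list alone, median -1.08), camera adjusted p = 5.45e-09, a call that held with an estimated correlation (adjusted p = 0.036). Inflammation genes rose in 6 of 17 and fell in 1, with Sele at 3.64 (camera adjusted p = 0.026; adjusted p = 0.447 with an estimated correlation). Lists not called at 48 h included cholesterol synthesis and uptake (6 of 17 higher, 1 lower, median 0.18, camera adjusted p = 0.15, with Idi1 at 1.09 and Cyp51 at 1.08) and immediate early genes (8 of 16 higher, 1 lower, with Fos at 3.28 and Egr2 at 3.15). Nor were DNA methylation enzymes (3 of 7 higher, 1 lower; Uhrf1 2.36, Dnmt1 1.28, Dnmt3a -0.84) called as a list. Endothelial markers had 1 of 14 higher and 5 lower, with Cldn5 at -1.72 and Emcn at 1.30 (camera adjusted p = 0.0729).

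The fit called 4109 genes at 48 h, 2359 higher and 1750 lower. It called 1931 when fitted to these 5 mice alone and 2728 without vehicle mouse 1. In vehicle mouse 4 the LCA minus RCA difference of Il1b was 0.56 against 5.72 to 7.12 in the other mice, and the mean difference of the neutrophil list was -0.07 against 3.21 to 4.25. That of the cell cycle list was -0.39 in this mouse and between 1.06 and 2.48 in the other vehicle-treated mice. The Gapdh end ratio was 3.95 ± 0.42 in the LCA and 4.33 ± 0.20 in the RCA (log2, SD, n = 5). Whether this gap, opposite in direction to that of 24 h, affected the 48 h calls was not tested.

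**Figure D2:**
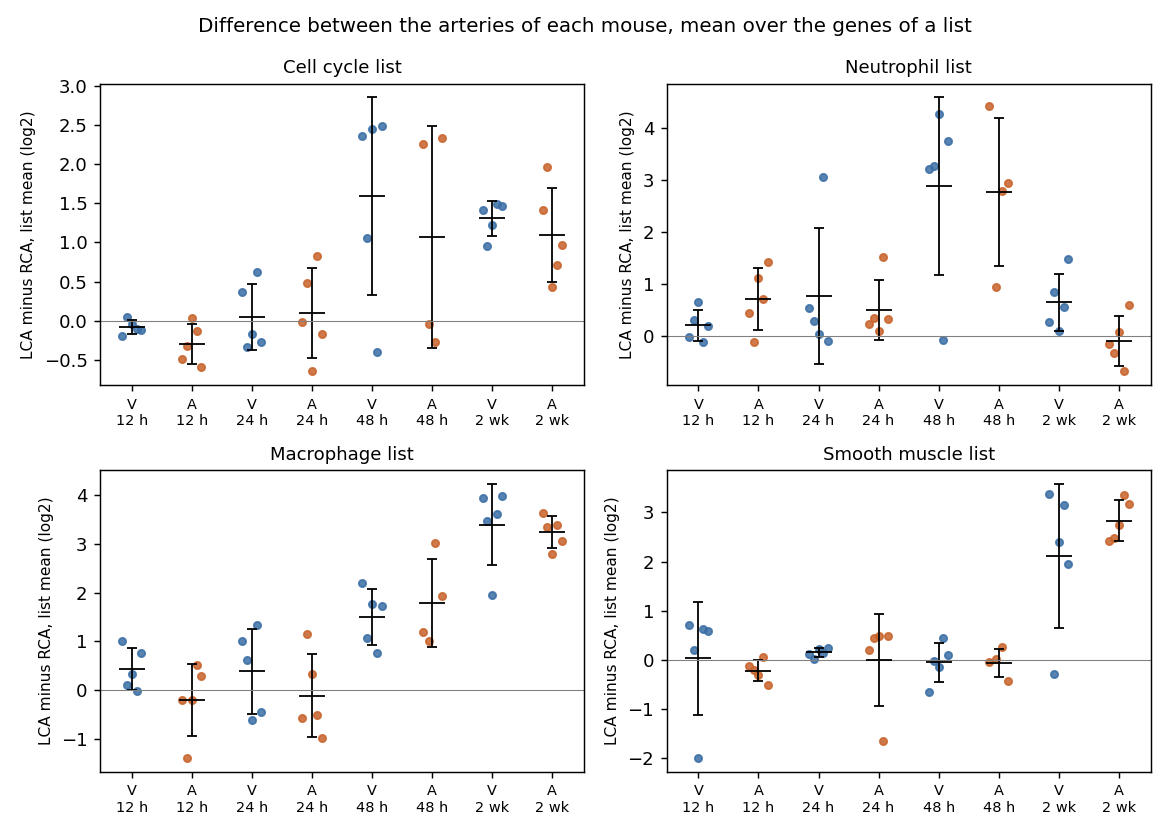
LCA minus RCA difference (log2) averaged over the genes of the cell cycle, neutrophil, macrophage and smooth muscle lists, for each mouse (points; blue vehicle, orange atorvastatin), with the mean and SD of each group as bars. At 48 h the neutrophil mean of 1 vehicle-treated mouse was -0.07 and those of the other 4 lay between 3.21 and 4.25, and the smooth muscle genes were highest at 2 weeks.

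After 2 weeks in vehicle-treated mice, macrophage, smooth muscle and matrix genes were among those that rose. Aif1, a macrophage gene (6.41, SE 0.61, adjusted p = 3.8e-10), Fscn1 (6.39), the TGF-beta binding protein gene Ltbp2 (6.29, SE 0.32, adjusted p = 1.6e-16) and Mpeg1 (5.90) rose most. They were followed by Ly86 (5.80), Gpr65 (5.75), Ctss (5.75) and the leukocyte common antigen gene Ptprc (5.67). Ptprr (-5.45), Klk10 (-5.39, SE 0.30, adjusted p = 9.2e-16), Fndc1 (-5.02), Igf2 (-4.81, SE 0.33), Syt7 (-4.19), Negr1 (-4.11), Clic5 (-4.08) and Rhpn2 (-3.97) fell most. This ranking too was limited to genes that moved the same way in 5 of 5 mice. Klf2 was lower by less than at 48 h (-1.34, SE 0.20), Klf4 was at -2.40 and Nos3 at -1.82 (SE 0.19, adjusted p = 2.2e-09). Vcam1 (-0.38, adjusted p = 0.15) and Icam1 (0.01, adjusted p = 0.96) were not called, and Insig1 fell (-0.81, SE 0.17). Vcam1 was at 1.07 in vehicle mouse 2 and between -1.14 and -0.09 in the others, and was called lower without that mouse (-0.74, adjusted p = 0.00107).

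Macrophage markers rose in 11 of 12 at 2 weeks, with Ms4a7 at 5.32 (SE 0.42), the complement gene C1qb at 5.01 (SE 0.56) and Lyz2 at 4.24 (median 3.33, camera adjusted p = 4.83e-13). That call held with an estimated correlation (adjusted p = 0.026). T cell markers rose in 4 of 5, namely Cd3g (1.89, SE 0.30), Cd3e (1.82), Cd2 (1.19) and Cd3d (0.97). The list had a camera adjusted p of 0.000147 (adjusted p = 0.062 with an estimated correlation). Dendritic cell genes had 4 of 5 higher and 1 lower, including Itgax (4.78) and Cd209a (2.61), at camera adjusted p = 0.0035 (adjusted p = 0.0873 with an estimated correlation). Antigen presentation genes rose in 7 of 11, among them Cd74 (3.41) and H2-Eb1 (3.33), at camera adjusted p = 0.0001 (adjusted p = 0.0873 with an estimated correlation). Neutrophil markers were not called as a list, with 1 of 7 higher and 0 when adjusted over the list alone.

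Extracellular matrix genes rose in 18 of 21 at 2 weeks (18 higher and 1 lower over the list alone), for example Postn (3.97, SE 0.60), the collagen genes Col1a1 (3.27) and Col3a1 (2.64), and Tnc (3.08). Their median was 1.46 (camera adjusted p = 6.31e-09; adjusted p = 0.0873 with an estimated correlation). Smooth muscle markers rose in 8 of 9, with Actg2 at 4.05 (SE 0.39), Itga8 at 3.11, the coactivator gene Myocd at 2.50 and Acta2 at 2.40. The list median was 2.40 (camera adjusted p = 8.41e-06; adjusted p = 0.157 with an estimated correlation). In vehicle mouse 2 the mean difference was -0.30 for the smooth muscle list and 0.08 for the matrix list, against at least 1.94 and 1.42 in the others. Itga8 was not called without mouse 1 (2.25, adjusted p = 0.0634). TGF-beta and mesenchymal transition genes rose in 6 of 15 and fell in 1, including Tgfbi (4.23) and Fn1 (1.69), at camera adjusted p = 0.00554 (adjusted p = 0.122 with an estimated correlation). Cell cycle genes rose in 14 of 25 (17 over the list alone), with Mki67 at 4.10 (SE 0.67), at camera adjusted p = 3.04e-06 (adjusted p = 0.382 with an estimated correlation). Of the inflammation list 7 of 17 rose and 1 fell, 8 and 1 over the list alone, led by the T cell chemokine gene Ccl5 (4.40, SE 0.27) and Cxcl10 (3.59). Its camera adjusted p was 0.00992 (adjusted p = 0.261 with an estimated correlation). Laminar flow-associated genes fell in 11 of 15 and rose in 1 (median -1.05, camera adjusted p = 1.67e-08, held at adjusted p = 0.026 with an estimated correlation). Among them Aqp1 was at -2.42.

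Endothelial markers were not called as a list at 2 weeks, with 6 of 14 lower and 2 higher (camera adjusted p = 0.0534): Icam2 was at -2.03 (SE 0.23), Robo4 at 1.79 and Emcn at 1.57. The YAP/TAZ list (3 higher, 2 lower of 11, including Ankrd1 at 3.19) had a median of -0.13 and a mean of 0.63. Cholesterol synthesis and uptake genes fell in 4 of 17 and rose in 1, with a median of 0.16 and a mean of -0.06; Sc5d was at -1.21. Erythroid (0 of 3 called, median -0.62) and adipocyte markers (0 of 4, median -0.60) did not pass. Of 3 lymphatic markers 2 fell, among them Lyve1 (-1.56). Platelet markers had 1 of 4 lower and 1 higher. Of the NRF2 and oxidative stress list, 3 of 13 fell and 1 rose, the heme oxygenase gene Hmox1 (2.18). In all, 3148 genes differed at 2 weeks, 1758 higher and 1390 lower. Vehicle mouse 2 lay apart from the other mice for several genes, with Klk10 at -3.09 against -6.35 to -5.58 and Fscn1 at 1.6 against 7.4 to 7.92.

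Across the 4 times, the LCA minus RCA difference of 3728 genes changed in vehicle-treated mice (limma F test). The smallest p belonged to the collagenase gene Mmp13, Slamf9 (adjusted p = 6.2e-13), Ltbp2, Cd72, Ccl5, Cd83, Pkib, Fgd2, Tlr12 and Krt80. At all 4 times 24 genes were higher in the LCA, for example Angpt2, Ccn2, Depp1, Edn1, Gadd45a, Gja4, Frzb and Sox4, and 62 were lower, for example Klf2, Klk10, Icam2, Timp3, Tcf23, Nrm, Dll1, Zbtb46 and Acvrl1. A further 299 genes were higher at one time and lower at another. Independent mice at 12 h and 24 h shared 95 higher and 92 lower genes (10.7 and 8.6 expected from independent lists), with 1 in opposite directions. At 24 h and 48 h, 164 genes were higher at both (169.7 expected) and 260 lower at both (124 expected), and 217 went in opposite directions. At 48 h and 2 weeks 953 higher and 824 lower genes were shared (365.6 and 214.4 expected), with 34 opposite. All these lists came from the same fit with a shared variance per gene, which alone can raise the overlap above the expected values.

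Between 48 h and 2 weeks the signed LCA minus RCA difference rose for 417 genes and fell for 236. Neutrophil markers fell, 4 of 7 members and 6 over the list alone (median -2.39, camera adjusted p = 0.00012; adjusted p = 0.142 with an estimated correlation). Smooth muscle genes rose, 5 of 9 members (median 2.19, camera adjusted p = 1.96e-09; adjusted p = 0.062 with an estimated correlation). Matrix genes did so in 11 of 21 (median 1.38, camera adjusted p = 5.34e-12; adjusted p = 0.062 with an estimated correlation) and macrophage genes in 6 of 12 (median 1.76, camera adjusted p = 8.63e-08; adjusted p = 0.0824 with an estimated correlation). T cell genes rose in 4 of 5 (median 1.32, camera adjusted p = 4.23e-08), held with an estimated correlation (adjusted p = 0.00695). From 12 h to 48 h the difference changed for 2199 genes, and from 12 h to 24 h for 0, with limma. The 12 h to 48 h change took in the cell cycle list, 19 of 25 higher (median 1.66, camera adjusted p = 4.6e-10; adjusted p = 0.418 with an estimated correlation).

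In mice given atorvastatin the same comparison of arteries gave 191 genes at 12 h (86 higher, 105 lower), 1485 at 24 h (827 higher, 658 lower), 3612 at 48 h (1887 higher, 1725 lower) and 3396 at 2 weeks (1649 higher, 1747 lower). The 12 h count was 12 in a fit to those 5 mice alone, 125, 85 and 102 without mouse 7, 8 or 10 and 323 without mouse 9. At 24 h it was 974 without mouse 8 and 824 without mouse 10, and at 48 h 2092 without mouse 6 and 2135 without mouse 9. The 12 h call of Angpt2 below was lost without mouse 6, 7, 8 or 9 and the 24 h call of Fmo1 without any 1 of the 5 mice. At 12 h Depp1 (2.74), Gadd45a (2.37), Angpt2 (2.17, SE 0.59, adjusted p = 0.046), Cdo1 (1.96) and Frzb (1.96) rose most. Klf2 (-3.04, SE 0.20, adjusted p = 8.3e-13), Tcf23 (-2.58), Ptp4a3 (-2.23) and Zbtb7c (-2.04) fell most at that time. At 24 h Depp1 (3.09), Sox4 (2.50), Cxcl2 (2.47), Klf15 (2.38) and Fmo1 (2.20) rose, and Nrm (-4.04), Igfbp5 (-3.22), Mob2 (-3.19) and Tcf23 (-3.12) fell. At 48 h S100a9 (5.18, SE 0.88), Mpeg1 (5.14), Chil3 (5.12), Ptprc (5.12) and Fscn1 (5.01) rose. Klk10 (-4.48, SE 0.34), Ptprr (-4.04), Spock2 (-3.62), Serpina1b (-3.42) and Fam107a (-3.37) fell at that time. At 2 weeks Fscn1 (6.79), Ltbp2 (6.47, SE 0.32, adjusted p = 3e-17), P4ha3 (6.10), Aif1 (5.81) and Gpr65 (5.71) rose, whereas Ptprr (-6.45), Klk10 (-6.14, SE 0.30), Igf2 (-6.11), Clic5 (-6.05) and Mal (-5.36) fell. All of these moved the same way in every mouse of their group (n = 5, and n = 4 at 48 h). Vcam1 was lower at 2 weeks (-1.11, SE 0.19, adjusted p = 2.3e-05), and its difference from the vehicle group was not past the threshold (-0.74, SE 0.27, adjusted p = 0.93), and was -0.37 without vehicle mouse 2. Over all genes, the LCA minus RCA changes of the treatments correlated across genes, which are not independent replicates, at r = 0.569, 0.785, 0.894 and 0.927 from 12 h to 2 weeks.

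Laminar flow-associated genes fell under atorvastatin at each time, with 3, 8, 11 and 12 of 15 lower at 12 h, 24 h, 48 h and 2 weeks and 1 higher at 2 weeks (camera adjusted p = 2.37e-10, 6.05e-08, 2.49e-06 and 4.87e-08). With an estimated correlation the adjusted p was 0.00751, 0.0545, 0.14 and 0.0348. Inflammation genes rose in 4, 7, 8 and 9 of 17 and fell in 0, 0, 1 and 2 (camera adjusted p = 1.4e-09, 7.16e-06, 0.000513 and 0.0154; adjusted p = 0.00751, 0.063, 0.236 and 0.268 with an estimated correlation). At 24 h 4 of 16 immediate early genes fell (camera adjusted p = 0.000608; adjusted p = 0.538 with an estimated correlation), and at 48 h 10 of 16 rose (median 1.11, camera adjusted p = 0.00518; adjusted p = 0.445 with an estimated correlation). Matrix genes were lower at 12 h, with 1 of 21 past the threshold (camera adjusted p = 0.022; adjusted p = 0.908 with an estimated correlation), and at 24 h, with 4 of 21 (camera adjusted p = 0.00585; adjusted p = 0.612 with an estimated correlation). Fibroblast markers were lower at the same times (medians -0.33 and -0.82, camera adjusted p = 0.0325 and 0.0393; adjusted p = 0.908 and 0.612 with an estimated correlation). Cell cycle genes were lower at 12 h, with 0 of 25 past the threshold (median -0.23, camera adjusted p = 0.0325, adjusted p = 0.917 with an estimated correlation). At 48 h cell cycle genes rose in 12 of 25, 13 over the list alone (median 1.08, camera adjusted p = 8.48e-05, adjusted p = 0.445 with an estimated correlation). The mean over that list was 2.26 and 2.34 in mice 6 and 9 and -0.04 and -0.27 in mice 7 and 8, and the median was 0.69 without mouse 6 and 0.60 without mouse 9. Neutrophil genes rose in 6 of 7 (median 2.48, camera adjusted p = 0.000513; adjusted p = 0.28 with an estimated correlation) and macrophage genes in 9 of 12 (camera adjusted p = 8.13e-05; adjusted p = 0.28 with an estimated correlation). At 2 weeks matrix genes rose in 17 of 21 (19 over the list alone, median 1.65, camera adjusted p = 5.28e-13) and macrophage genes in 11 of 12 (median 3.12, camera adjusted p = 7.57e-13), and both were called with an estimated correlation (adjusted p = 0.0348 each). Smooth muscle genes rose in 8 of 9 (median 3.06, camera adjusted p = 2.93e-08; adjusted p = 0.0835 with an estimated correlation). The T cell list was not called (2 of 5 higher, median 0.41, camera adjusted p = 0.205). Endothelial markers fell in 8 of 14 and rose in 2 at both 48 h and 2 weeks (camera adjusted p = 0.0218 and 0.0404; adjusted p = 0.445 and 0.461 with an estimated correlation). The count at 48 h was 215 in a fit to those 4 mice alone.

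Atorvastatin compared with vehicle in the ligated LCA gave 0 genes past the threshold at 12 h, 24 h, 48 h and 2 weeks and for the mean of the 4 times with limma. In these comparisons 577, 309, 476, 313 and 690 genes had an unadjusted p under 0.05, where 567 would be expected by chance. The counts at 12 h and 2 weeks rose above 0 when certain single mice were left out, as given further below. For the mean over the times in the LCA, the flow-related genes were not called: Klf2 -0.17 (SE 0.14), Klf4 -0.05 (SE 0.23), Nos3 0.00 (SE 0.10), Vcam1 -0.05 (SE 0.14), Icam1 0.02 (SE 0.06) and Klk10 0.04 (SE 0.21). At single times the laminar flow-associated list was higher in the LCA at 48 h (median 0.12, camera adjusted p = 0.0231; adjusted p = 0.418 with an estimated correlation) and the inflammation list lower at 2 weeks (median -0.27, camera adjusted p = 0.0267; adjusted p = 0.437 with an estimated correlation), with 0 members of either past the threshold in limma. The laminar call was lost without vehicle mouse 1 or 5 or atorvastatin mouse 7 or 8 (medians 0.07, 0.09, -0.06 and 0.06). The inflammation call was lost without vehicle mouse 3 or atorvastatin mouse 8 (medians -0.17 and -0.20). The sterol-responsive genes Sqle (-0.01, SE 0.20) and Insig1 (-0.07, SE 0.10) in the LCA, and Sqle (0.22, SE 0.17) and Insig1 (0.04, SE 0.06) in the RCA, were not called either. Of the 17 cholesterol synthesis and uptake genes measured, 0 passed in any comparison of atorvastatin with vehicle. Their list median was -0.04 in the LCA (camera adjusted p = 0.592) and -0.04 in the RCA (camera adjusted p = 0.5) over the mean of the times. Ebp of that list was higher in the LCA at 12 h when adjusted over the list alone (0.75, SE 0.22), and not over all genes (adjusted p = 0.56). Hmgcs1 was below the signal filter.

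In the unligated RCA, 5 genes differed between atorvastatin and vehicle at 12 h. Ube4a, a ubiquitin chain assembly factor gene, was higher (5.57 ± 0.66 with vehicle and 6.70 ± 0.12 with atorvastatin, log2, SD, n = 5 each; difference 1.13, SE 0.22, limma adjusted p = 0.0324). So was the lipid droplet hydrolase gene Ldah (0.94, SE 0.19, adjusted p = 0.0373). Dnmbp (-0.94, SE 0.18) and the base excision repair gene Mbd4 (-0.93, SE 0.18) were lower, both at adjusted p = 0.0324, and the fifth was a predicted gene. In each of the 4 named genes, 5 of 5 treated mice lay on that side of the vehicle mean. At 2 weeks the ARF exchange factor gene Cyth3 was higher (9.33 ± 0.25 and 10.07 ± 0.25, n = 5 each; 0.74, SE 0.13, limma adjusted p = 0.0237, 5 of 5 mice). At 24 h and 48 h 0 genes passed with limma (452 and 1211 at unadjusted p under 0.05). Over the mean of the 4 times Zbtb16, a transcription factor gene induced by glucocorticoids, was higher in the RCA by 1.18 (SE 0.21, adjusted p = 0.0334; 16 of 19 treated mice above the vehicle mean of their time). Gprin2 was lower (-0.72, SE 0.13, adjusted p = 0.0334; 17 of 19 below it). Zbtb16 differed by 0.48, 0.54, 1.99 and 1.70 in the RCA and by -0.13, 0.57, 1.40 and 2.05 in the LCA from 12 h to 2 weeks. For the mean of both arteries 0 genes passed with limma (1336 at unadjusted p under 0.05), with Zbtb16 at 1.08 (SE 0.20, adjusted p = 0.0538, 17 of 19 above the vehicle mean of their time). Some other settings and omissions of single mice raised that count above 0, as given further below.

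These calls in the RCA were few and depended on settings: with the title code number of each mouse as a block, 0 genes were called at 12 h, 0 at 2 weeks and 1 over the mean of the times. A fit to the mice of that time alone called 0 at 12 h and 0 at 2 weeks. Without vehicle mouse 2 the count at 12 h was 0, and without atorvastatin mouse 9 it was 194. Leaving out each mouse in turn ended the call of Zbtb16 in 15 of 39 omissions, of Gprin2 in 23 of 39, of Cyth3 in 6 of 10 and of the named genes at 12 h in 6 or 7 of 10. The Gapdh end ratio at 12 h in the RCA was 4.74 ± 0.31 with vehicle and 4.21 ± 0.21 with atorvastatin (log2, SD, n = 5 each). At 48 h in the RCA it was 4.33 ± 0.20 with vehicle (n = 5) and 3.81 ± 0.48 with atorvastatin (n = 4).

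Several gene lists shifted between treatments although 0 of their members passed over all genes. At 2 weeks in the LCA, T cell genes were lower under atorvastatin (median -0.61, 4 of 5 lower over the list alone, camera adjusted p = 2.56e-11, held with an estimated correlation at adjusted p = 0.00831). YAP/TAZ targets were higher (median 0.30, camera adjusted p = 0.000221, held at adjusted p = 0.0386 with an estimated correlation). That estimated p was 0.161 without vehicle mouse 2, with a median of 0.17, 0.0815 without atorvastatin mouse 8 and 0.129 without mouse 9. Smooth muscle genes were higher as well (median 0.72, camera adjusted p = 1.06e-08; adjusted p = 0.0929 with an estimated correlation), as were matrix genes (median 0.27, camera adjusted p = 4.14e-05; adjusted p = 0.437 with an estimated correlation). Vehicle mouse 2 carried much of these differences: without it the median was 0.19 for smooth muscle genes (camera adjusted p = 0.0292) and -0.006 for matrix genes, which were then not called (camera adjusted p = 0.985). Interferon-response (median -0.31, camera adjusted p = 0.00168) and antigen presentation genes (median -0.41, camera adjusted p = 0.00433) were lower at 2 weeks, and each had adjusted p = 0.532 with an estimated correlation. Neither was called without vehicle mouse 3 (medians -0.16 and -0.24, camera adjusted p = 0.347 and 0.133). At 48 h in the LCA, cell cycle genes were lower (median -0.72, camera adjusted p = 2.32e-05; adjusted p = 0.435 with an estimated correlation) and fibroblast markers higher (median 0.76, camera adjusted p = 0.000603; adjusted p = 0.418 with an estimated correlation). The cell cycle mean in the LCA was uneven within both treatments, at 5.83 in vehicle mouse 4 and 7.01 to 8.31 in the other vehicle mice, and at 5.63 and 5.97 in atorvastatin mice 7 and 8 and 8.14 and 7.61 in mice 6 and 9. Without atorvastatin mouse 7 neither the cell cycle (median -0.20, camera adjusted p = 0.453) nor the fibroblast list (median 0.55, camera adjusted p = 0.0937) was called. Without mouse 8 the fibroblast list was not called (median 0.25, camera adjusted p = 0.249) and the cell cycle median was -0.29. In the RCA at 24 h immediate early genes (median 0.50), fibroblast (median 0.70, both at camera adjusted p = 0.00021) and adipocyte markers (median 1.62, camera adjusted p = 0.00564) were higher, each at adjusted p = 0.502 with an estimated correlation. Without atorvastatin mouse 7 of that time the immediate early (median 0.19, camera adjusted p = 0.279) and adipocyte lists (median 1.01, camera adjusted p = 0.196) were not called. At 2 weeks in the RCA erythroid markers were higher (median 1.66, camera adjusted p = 0.00159; adjusted p = 0.209 with an estimated correlation). This call was lost without atorvastatin mouse 6 (median 1.11, camera adjusted p = 0.0721).

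Whether atorvastatin altered the LCA minus RCA difference itself was tested with the interaction of treatment and artery. At 12 h Ube4a passed (-1.73, SE 0.30, adjusted p = 0.0159), with a difference of 1.12 ± 0.75 under vehicle and -0.61 ± 0.56 under atorvastatin (SD, n = 5 each). Much of this lay in the unligated RCA, where Ube4a was higher by 1.13 under atorvastatin. The Gapdh end ratio at 12 h was 4.74 with vehicle and 4.21 with atorvastatin in the RCA, and 4.82 and 4.88 in the LCA. RNA quality was thus not separated from this interaction. At 2 weeks the deoxyribonuclease gene Dnase1l3 (2.78 ± 1.09 under vehicle and 0.85 ± 0.44 under atorvastatin; -1.93, SE 0.32) and Mmp13 (4.15 ± 0.57 and 2.34 ± 0.85; -1.80, SE 0.30) passed, both at limma adjusted p = 0.00564 and in 5 of 5 mice. At 24 h, 48 h and for the mean of the times 0 genes passed with limma (296, 581 and 422 at unadjusted p under 0.05). A fit to the mice of a time alone called 0 at 12 h and 0 at 2 weeks, and a fit without pairing the arteries called 0 at 2 weeks. The Ube4a call ended in 5 of 10 omissions of 1 mouse, that of Mmp13 without atorvastatin mouse 7 (-1.53, adjusted p = 0.0569) and that of Dnase1l3 in 0 of 10.

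T cell genes had the lowest camera p among the lists in this test at 2 weeks (median -0.73, 4 of 5 lower over the list alone, camera adjusted p = 1.31e-07), a call that held with an estimated correlation (adjusted p = 0.00703). Over all genes no member passed: Cd3g was at -1.55 (SE 0.43, adjusted p = 0.38), Cd3e at -1.31 (SE 0.42, adjusted p = 0.68) and Cd2 at -0.73 (SE 0.20, adjusted p = 0.34). The mean of the T cell genes rose from RCA to LCA by 1.3 ± 0.29 under vehicle and by 0.35 ± 0.9 under atorvastatin (SD, n = 5 each; exact two-sided permutation p = 0.0476, adjusted p = 0.131 over 3 such tests), and was positive in 5 of 5 and 3 of 5 mice. Atorvastatin mouse 8 had an RCA value of 5.76, above that of its LCA. The mean rise under atorvastatin was 0.66 without this mouse and 0.08 without mouse 7. In the LCA it was 5.55 ± 0.84 and 4.69 ± 0.41 (exact two-sided permutation p = 0.0873), and in the RCA 4.25 ± 0.67 and 4.35 ± 0.85 (exact two-sided permutation p = 0.841). Matrix (median 0.24, camera adjusted p = 9.01e-05) and smooth muscle genes (median 0.69, camera adjusted p = 0.000101) were also shifted at 2 weeks, at adjusted p = 0.423 each with an estimated correlation. Without vehicle mouse 2 neither was called (medians -0.03 and 0.06, camera adjusted p = 0.614 and 0.31). Cell cycle genes were shifted at 48 h (median -0.70, camera adjusted p = 0.0152; adjusted p = 0.954 with an estimated correlation). The 48 h call was lost without vehicle mouse 1, 3 or 5 (medians -0.43, -0.39 and -0.46) or atorvastatin mouse 7 or 8 (medians -0.21 and 0.02).

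**Figure D3:**
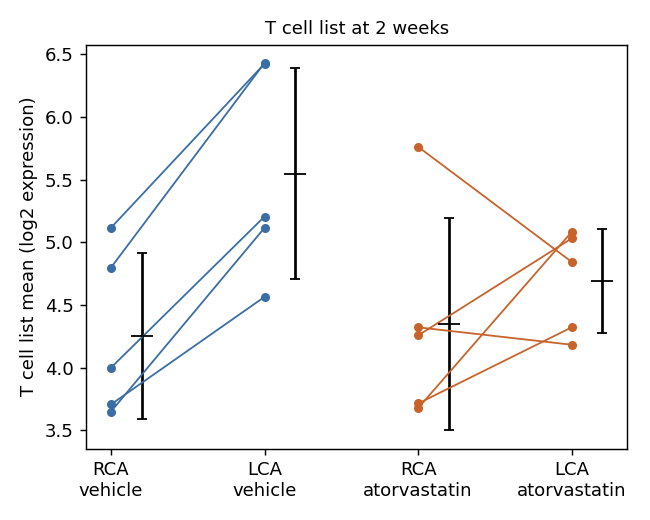
Mean log2 expression of the T cell list in the RCA and LCA of each mouse at 2 weeks, with the arteries of a mouse joined by a line (blue vehicle, orange atorvastatin) and the mean and SD of each group as bars. The mean rise from RCA to LCA was 1.3 with vehicle and 0.35 with atorvastatin, or 0.66 without atorvastatin mouse 8.

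The control RCA also changed with time in vehicle-treated mice, with 3035 genes past the limma F test. Sphk2 (adjusted p = 7.3e-14), the clock output gene Dbp (adjusted p = 3.8e-13), Ripor2, Rnf144b, Nr1d2, Col6a3, Arntl, Cry1, the metallothionein gene Mt1 and Cdkn1a had the smallest p. From 12 h to 24 h in the RCA Dbp rose by 4.40 (SE 0.34, adjusted p = 3.66e-11), Nr1d2 by 2.17 (SE 0.24) and Per3 by 1.53, whereas Npas2 (-3.09, SE 0.37), Arntl (-2.85, SE 0.31), Nfil3 (-2.02) and Cry1 (-1.32) fell. In all 12 of 13 circadian clock genes passed, a list chosen after the data were seen. Under atorvastatin Dbp rose by 3.33 and Arntl was at -2.38, with 9 of 13 past the threshold. Over the same interval 2055 genes changed in the RCA of vehicle-treated mice, 1133 higher and 922 lower at 24 h. Endothelial markers rose in 6 of 14 (10 over the list alone, median 0.50, camera adjusted p = 0.0021; adjusted p = 0.96 with an estimated correlation). The Gapdh end ratio also fell over this interval, from 4.74 ± 0.31 at 12 h to 4.04 ± 0.24 at 24 h. It was 4.33 ± 0.20 at 48 h and 3.81 ± 0.28 at 2 weeks (log2, SD, n = 5 each). With that ratio as a covariate, added after the data were seen, 400 genes changed over time in the RCA. Without the vehicle mouse 4 of 12 h 1974 did. From 24 h to 48 h 0 genes changed in the RCA with limma, and from 48 h to 2 weeks 74 (11 higher, 63 lower).

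**Figure D4:**
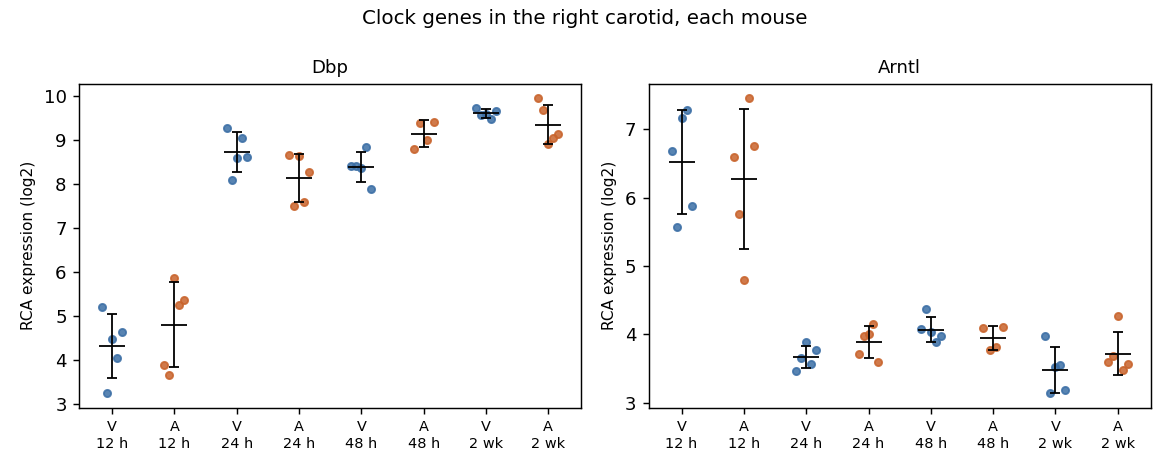
RCA expression (log2) of the circadian clock genes Dbp and Arntl for each mouse (points; blue vehicle, orange atorvastatin) at 12 h, 24 h, 48 h and 2 weeks, with the mean and SD of each group as bars. From 12 h to 24 h Dbp rose by 4.40 and Arntl fell by 2.85 in vehicle-treated mice.

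In the LCA itself 5612 genes changed over time with vehicle, those with the smallest p being Dock10 (adjusted p = 1.4e-11), Vwc2, Slamf9, Mmp13, Hpgds, Slc43a3, Lair1, Fgd2, Pkib and Spaar. From 48 h to 2 weeks smooth muscle genes rose in 8 of 9 (median 2.41, camera adjusted p = 3.92e-16) and T cell genes in 5 of 5 (median 1.42, camera adjusted p = 1.21e-09). Both calls held with an estimated correlation (adjusted p = 0.0117 each). Cell cycle genes fell in 9 of 25 (median -0.83, camera adjusted p = 0.000638; adjusted p = 0.506 with an estimated correlation). Cholesterol synthesis and uptake genes fell in 6 of 17 (median -0.53, camera adjusted p = 0.00164; adjusted p = 0.162 with an estimated correlation). The Gapdh end ratio in the LCA was 4.82 ± 0.30 at 12 h, 4.98 ± 0.47 at 24 h and 3.95 ± 0.42 at 48 h. Degradation was therefore not separated from time in the LCA either. With the title code number as a block 2908 genes changed over time in the LCA. Across the 29 lists tested in 24 comparisons, 104 of 696 tests were called by camera at the preset correlation and 15 with an estimated correlation, all 15 among the 104. Fry, which tests whether the genes of a list move to one side without comparing them with other genes, called 85, of which 57 were among the 104.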

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

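The tests of a swapped artery, of the title code, of clock genes with the Gapdh end ratio as a covariate and of smooth muscle RNA or endothelial share, and the choice to leave out both 48 h mice, were made only after the results were seen. In 37 of 391 sets of values, each of 1 gene or list in 1 group of mice, a value lay far outside the others. Chance gives such a value in about 1 in 20 independent sets. These sets share the same mice and are not independent, so that the share cannot be judged against it.

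At 12 h with vehicle, the LCA minus RCA difference (log2) of Col6a3 was -0.83 in mouse 2 (others -2.51 to -2.03) and that of Vcam1 was 0.94 in mouse 2 (others 0.35 to 0.45). The Notch list mean was 0.38 in mouse 4 (others -0.05 to 0), and the smooth muscle list mean was -2 in mouse 3 (others 0.2 to 0.72). At 24 h with vehicle Mob2 was -1.81 in mouse 2 (others -3.01 to -2.78), the immediate early gene list -0.98 in mouse 3 (others -0.22 to 0.05), the neutrophil list 3.05 in mouse 4 (others -0.09 to 0.55) and the platelet list 1.75 in mouse 4 (others -0.14 to 0.37). At 48 h with vehicle, in mouse 4, Il1b was 0.56 (others 5.72 to 7.12), Slfn4 0.16 (others 5.11 to 6.68) and the neutrophil list -0.07 (others 3.21 to 4.25). The matrix list was 0.66 in mouse 5 (others -0.02 to 0.13) and the adipocyte list 2.38 in mouse 2 (others -1.02 to -0.09).

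At 2 weeks with vehicle, mouse 3 had lower macrophage values: Aif1 3.99 (others 6.63 to 7.39), Ly86 3.79 (others 6.01 to 6.68) and the macrophage list 1.96 (others 3.48 to 3.99). Mouse 2 had smaller changes in Fscn1 (1.6, others 7.4 to 7.92), Ptprr (-4.32, others -5.92 to -5.57), Klk10 (-3.09, others -6.35 to -5.58), Fndc1 (-3.1, others -5.64 to -5.35), Igf2 (-2.47, others -5.89 to -5.02), Syt7 (-2.58, others -4.86 to -4.31), Rhpn2 (-2.96, others -4.37 to -4.08) and the hypoxia list (0.09, others 0.17 to 0.19). In the same mouse the smooth muscle list was at -0.30 and the matrix list at 0.08, with the macrophage list at 3.48.

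Under atorvastatin at 12 h Frzb was 2.85 in mouse 8 (others 1.62 to 1.89), Klf4 -1.53 in mouse 10 (others -1 to -0.91), Nos3 -1.82 in mouse 8 (others -0.93 to -0.59), Insig1 0.02 in mouse 9 (others 0.5 to 0.67) and the platelet list -0.7 in mouse 7 (others 0.17 to 0.41). At 24 h Fmo1 was 2.05 in mouse 9 (others 2.23 to 2.25), Klk10 -1.9 in mouse 7 (others -3.4 to -3.08), the TGF-beta list -0.01 in mouse 7 (others -0.35 to -0.28), the smooth muscle list -1.66 in mouse 9 (others 0.2 to 0.49) and the neutrophil list 1.51 in mouse 9 (others 0.1 to 0.35). At 48 h the antigen presentation list was 0.12 in mouse 9 (others 0.96 to 1.05) and the matrix list 0.86 in mouse 8 (others 0.11 to 0.24). At 2 weeks the erythroid list was 1.63 in mouse 10 (others -2.18 to -1.63).

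Differences between groups passed their own test for Ube4a at 12 h (-1.73), Dnase1l3 (-1.93), Mmp13 (-1.8) and the T cell list (-0.73) at 2 weeks, each the effect of atorvastatin on the LCA minus RCA difference. Other tests did not exclude chance: 22 of 100 splits reached the 1 gene of 12 h and 14 of 100 the 2 genes of 2 weeks, and the exact permutation test of the T cell list mean had an adjusted p of 0.131. The LCA minus RCA difference of 3728 genes changed over the 4 times with vehicle.

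At 48 h the LCA of vehicle mouse 4 and of atorvastatin mouse 7 showed little of both the cell cycle and the neutrophil rise; atorvastatin mouse 8 had no cell cycle rise either (-0.27) but a neutrophil list mean of 2.78. An RCA carrying an LCA label was argued against, since Klf2 was at -2.89 and -2.35 and Klk10 at -3.58 and -3.97 in these mice, within or near the -3.34 to -1.87 and -5.3 to -3.74 of the other 7. The title code of atorvastatin mouse 7 was argued against too, because vehicle mouse 1 shared it and had a rise of 2.36. An LCA of 24 h labelled 48 h stays open: the profiles were closer to the mean of the 24 h group (r = 0.434 and 0.581 over 5088 genes) than to the other 48 h mice (0.351 and 0.516), a difference of -0.083 in vehicle mouse 4. Other values of these LCA arrays went both ways. Klf2 (6.50 and 6.95), Klk10 (6.29 and 6.54) and the Gapdh end ratio (3.77 and 3.97) lay below every 24 h LCA array (lowest 7.09, 6.77 and 4.12). Dbp (8.67 and 8.93) lay within the 24 h range (7.92 to 9.61) and above the other 48 h LCA arrays (highest 7.51). The antigen presentation list mean of vehicle mouse 4 was 9.69 in the LCA and 9.33 in the RCA, above every 24 h LCA array (highest 8.21). Its interferon-response list mean in the LCA, 8.52, was above them too (highest 7.995). Atorvastatin mouse 7 lay within the 24 h LCA range for both lists (7.68 and 7.63). Why both arteries of vehicle mouse 4 had such values was not tested. A slower response in these mice also stays open and was not tested.

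Genes of the RCA changed widely between 12 h and 24 h with vehicle, although this artery was not ligated. For genes other than clock genes RNA degradation cannot be told apart from time. The Gapdh end ratio differed by 0.71 between these times with vehicle and by 0.11 under atorvastatin. Yet the slope of the atorvastatin changes on the vehicle changes was 0.49, next to the bound of 0.5 set beforehand, so that it decided neither way. The slope was taken over all 2055 genes called with vehicle, clock genes included. Choosing genes by their vehicle change can itself lower such a slope. Over these genes, which are not independent replicates, the changes of the treatments correlated at r = 0.85. The end ratio of b-actin in the RCA with vehicle was -0.083 ± 0.378 at 12 h and -0.275 ± 0.185 at 24 h (log2, SD, n = 5 each). It was not used as a covariate. The fit called 2055 genes with vehicle, 51 with the Gapdh end ratio as a covariate and 113 under atorvastatin. With the covariate the 2043 called genes other than clock genes had a median size of 0.48 (median SE 0.22) instead of 0.67 (0.19), so that calls ended through smaller changes and larger SE. Degradation as the whole cause was argued against for clock genes: 8 of 13 still passed, with Dbp at 4.01 (SE 0.40; 4.40, SE 0.34 without the covariate), Arntl at -2.63 (SE 0.38; -2.85, SE 0.31) and Nr1d2 at 2.42 (SE 0.28; 2.17, SE 0.24). Of the 4 calls lost, Per1 (0.55, SE 0.34; 1.18, SE 0.31) and Cry1 (-0.96, SE 0.27; -1.32, SE 0.23) had smaller changes, and Tef (0.57, SE 0.19; 0.43, SE 0.15) and Hlf (0.75, SE 0.20; 0.68, SE 0.16) larger ones with a larger SE. A difference in the time of day is a candidate explanation for part of it, since 9 of 13 clock genes changed under atorvastatin as well, and the surgery itself was not tested, as every mouse was operated.

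At 2 weeks smooth muscle and matrix genes rose in the LCA. A lower share of endothelial RNA with a common rise of all other RNA was argued against. Fibroblast markers were at -0.69 (SD 1.25) and smooth muscle markers at 2.11 (SD 1.46), a difference of -2.8 (SE 0.86) where a common shift would move both alike. These values cannot exclude a lower endothelial share with more RNA of some cell types and not of fibroblasts. The endothelial list mean was -0.29, with 6 of 14 markers lower and 2 higher. RNA from smooth muscle cells in the flushed material cannot be told apart from a change in the endothelial cells themselves: the 8 of 9 smooth muscle markers that rose are the pattern itself and decide nothing, and no other value was tested.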

How the results depend on the processing

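The settings that left out both 48 h mice or used the Gapdh end ratio, and the leave-one-out tests of gene lists, were chosen only after the results were seen. Over all alternatives, 471 counts stayed within 1.5 times their main value and 120 moved by more; of the values for single named genes 59986 kept their direction and side of the threshold, 881 lost a call, 92 gained one and 1 reversed. That was Tgfbr2 at 24 h with vehicle, from 0.57 to -0.008 with the mean of all probe sets of a gene. Low array signal limits what can be seen, as genes under the signal filter were not tested; no other cause was tested except where fewer mice or genes entered a fit.

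With only the groups compared in the fit, which leaves fewer mice to estimate the spread, LCA against RCA gave 72 genes at 12 h and 1931 at 48 h with vehicle and 12 and 215 with atorvastatin. The same setting gave 0 for atorvastatin in the RCA at 12 h and 2 weeks and 0 for its interaction with the artery at 12 h and 2 weeks. No signal filter gave 0 over the mean of times in the RCA. The stricter filter gave 3 in the RCA at 12 h, 2 for both arteries and 0 for the interaction at 2 weeks. The mean of all probe sets gave 0 in the RCA at 12 h, 1 for both arteries and 0 for the interaction at 12 h. Trend and robust options gave 2 in the RCA at 2 weeks and 2 for both arteries, and renewed quantile normalization 2 in the LCA and 0 in the RCA at 2 weeks. With the title code number as a block the RCA counts for atorvastatin were 0 at 12 h, 2 at 48 h, 0 at 2 weeks and 1 over the mean of times, and 2908 genes changed over time in the LCA. Without both 48 h mice (vehicle 4 and atorvastatin 7) 1 gene was called for atorvastatin in the RCA at 48 h, and LCA against RCA gave 4740 and 4420 genes at 48 h. With the Gapdh end ratio as a covariate 400 genes changed over time in the RCA. Of the list calls 15 were made with an estimated correlation, against 104 at the preset one. A higher correlation raises the camera p, and the preset value was 0.01. Estimated from the LCA minus RCA differences it was, for example, 0.592 for the cell cycle, 0.583 for the smooth muscle and 0.396 for the macrophage list, but -0.004 for the coagulation list. For the other settings the cause was not tested.

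Pairing of the arteries came from the labels and was part of the main design. With no replicate block the interaction at 2 weeks gave 0 genes, and with the replicate block as a random effect (consensus correlation 0.092) 1; the unpaired fit gave 211, 1362, 3891 and 2959 genes for LCA against RCA with vehicle, and no other call changed by over 1.5 times.

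Leaving out each mouse in turn moved LCA against RCA with vehicle to 147 to 195 genes at 12 h, 898 to 1367 at 24 h, 2728 to 4664 at 48 h and 2378 to 3122 at 2 weeks. Changes over 1.5 times came at 12 h without vehicle mouse 1 (167), 2 (147), 3 (147) or 5 (175), at 24 h without 2 (1047), 3 (898) or 5 (920) and at 48 h without 1 (2728). With atorvastatin the ranges were 85 to 323, 824 to 1222, 2092 to 4336 and 2689 to 3002; such changes came at 12 h without mouse 7 (125), 8 (85), 9 (323) or 10 (102), at 24 h without 8 (974) or 10 (824) and at 48 h without 6 (2092) or 9 (2135). The change over time ranged from 2881 to 4453 for the difference, 1974 (without vehicle mouse 4 of 12 h) to 3409 in the RCA and 4650 to 6420 in the LCA.

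For atorvastatin in the LCA the ranges were 0 to 4 at 12 h, 0 to 0 at 24 h and 48 h, 0 to 7 at 2 weeks and 0 to 0 over the mean. At 12 h this came without vehicle mouse 2 (2) or atorvastatin mouse 6 (4) or 9 (1), and at 2 weeks without vehicle mouse 3 (2), 4 (7) or 5 (7) or atorvastatin mouse 6 (4) or 8 (1). In the RCA the ranges were 0 to 194 at 12 h, 0 to 2 at 24 h, 48 h and 2 weeks, and 0 to 6 over the mean, where 27 of 39 omissions moved the count of 2. At 12 h each omission moved it: 9, 0, 0, 0 and 57 without vehicle mice 1 to 5, and 0, 3, 0, 194 and 1 without atorvastatin mice 6 to 10. At 2 weeks Cyth3 or any other call was absent (0) without vehicle mouse 2 or 4 or atorvastatin mouse 8, 9 or 10, and without vehicle mouse 5 there were 2. Both arteries gave 0 to 6. For the interaction the ranges were 0 to 1 at 12 h, 0 to 0 at 24 h, 48 h and over the mean, and 1 to 12 at 2 weeks. At 12 h it was 0 without vehicle mouse 2, 4 or 5 or atorvastatin mouse 6 or 8. At 2 weeks it was 12, 5 and 7 without vehicle mouse 1, 2 or 5 and 9, 1 and 5 without atorvastatin mouse 6, 7 or 8. The median of the T cell list at 2 weeks stayed called, at -0.941 to -0.637 for the interaction and -0.914 to -0.488 in the LCA. Of the other 29 list calls between treatments at single times, all but 3 were lost or reversed without at least 1 mouse. The exceptions were YAP/TAZ targets and smooth muscle genes in the LCA at 2 weeks and fibroblast markers in the RCA at 24 h. At 2 weeks the matrix median ranged from -0.006 to 0.431 in the LCA and from -0.03 to 0.551 for the interaction, lowest without vehicle mouse 2 in both. At 48 h the cell cycle median of the interaction ranged from -1.155 to 0.019, highest without atorvastatin mouse 8. In the LCA at 48 h the laminar flow-associated median ranged from -0.062 (without atorvastatin mouse 7) to 0.255 and the immediate early median from -0.28 (without atorvastatin mouse 8) to 0.536. The inflammation median in the RCA at 2 weeks ranged from -0.046 to 0.008, highest without vehicle mouse 1.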

Other observations

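The split of samples below was planned; the choice of the single arrays and genes named here was made only after the results were seen, as were the tests of a swapped artery, of the title code and of smooth muscle RNA or endothelial share.

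Single genes of some lists were called at 24 h or 48 h in vehicle-treated mice where the list as a whole showed no direction at 24 h: 2 of 15 interferon-response genes (camera adjusted p = 0.61) and 2 of 16 immediate early genes (camera adjusted p = 0.213) were called at that time. The interferon-response gene Rsad2 was higher in the LCA at 24 h (1.45), whereas Ifit3 (-1.68) and Ifit1 (-1.65) were lower at 48 h. Nr4a1, an immediate early gene, was lower at 24 h (-1.77), and Fos (3.28) and Egr2 (3.15) were higher at 48 h. Cyclin D1 (Ccnd1) was lower at 24 h (-1.36), before the rise of Rrm2 (2.80) and Cdk1 (2.21) at 48 h. S100a10 and annexin A2 (Anxa2), which together bind plasminogen activators on endothelium, were lower at 24 h (-1.75 and -1.36), the urokinase gene Plau was higher at 48 h (2.00) and 2 weeks (2.31), and the tissue plasminogen activator gene Plat was lower at 2 weeks (-2.36). Uhrf1 and Dnmt1, which copy DNA methylation after replication, were higher at 48 h (2.36 and 1.28) with the de novo enzyme gene Dnmt3a lower (-0.84), and the demethylation gene Tet2 was higher at 2 weeks (0.73).

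Lists with fewer than 3 tested genes were not tested as lists. Of the B cell list, Cd22 (-0.03, adjusted p = 0.892) and Fcrla (0.05, adjusted p = 0.824) were not called at 2 weeks with vehicle. Of the Schwann cell list Pmp22 was lower in the LCA at 48 h (-1.02, adjusted p = 0.000127) and 2 weeks (-1.33, adjusted p = 1.92e-06). Of the skeletal muscle list Mylpf (-0.01) and Tnnc2 (-0.18) were not called at 2 weeks with vehicle, and of the thyroid list 0 genes were tested.

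Single arteries stood apart. The RCA of vehicle mouse 4 at 48 h had a T cell list mean of 5.38 and an inflammation list mean of 8.33, against at most 3.88 and 7.28 in the RCA of the other vehicle mice of that time. At 2 weeks under atorvastatin the neutrophil list in the RCA was at 4.82, 4.74 and 5.11 in mice 6, 7 and 9, and at 3.88 and 3.80 in mice 8 and 10. The erythroid list in the RCA was at 9.27, 6.58, 8.26, 8.51 and 5.30 in mice 6 to 10, and at 4.08, 5.48, 6.46, 5.14 and 8.31 in vehicle mice 1 to 5.

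Other splits of the mice were fitted for each count. For LCA against RCA, exchanging the arteries of some mice gives 16 splits (8 under atorvastatin at 48 h), too few for a share under 0.05. With vehicle the real counts of 271, 1620, 4109 and 3148 were reached by 1, 1, 1 and 1 split, the real one, and the highest other values were 10, 3, 3767 and 1471. With atorvastatin the counts of 191, 1485, 3612 and 3396 were reached by 2, 1, 1 and 1, with 327, 73, 2964 and 1149 as the highest others. For the change over time 1 of 100 splits, the real one, reached 3728 genes for the difference, 3035 in the RCA and 5612 in the LCA (highest others 1769, 1309 and 2227), so that chance was excluded. For atorvastatin in the RCA over the mean of the times 4 of 100 splits reached the 2 genes called (highest other 18). That share is under 0.05 for this comparison taken alone, but it was 1 of 16 comparisons of atorvastatin with vehicle, with no adjustment for their number; the count was 0 with no signal filter and moved in 27 of 39 omissions of a mouse, so that chance stays open for these 2 genes. Chance was not excluded for the RCA at 12 h (20 of 100 splits reached 5 genes, highest other 1746) or 2 weeks (15 of 100 reached 1, highest other 7), nor for the interaction at 12 h (22 of 100 reached 1, highest other 336) or 2 weeks (14 of 100 reached 2, highest other 20).

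The comparisons with 0 genes were reached by 100 of 100 splits. Their highest other values were 585, 2, 2874 and 7 in the LCA from 12 h to 2 weeks and 362 over the mean, 3 and 6 in the RCA at 24 h and 48 h, 39 for both arteries, and 1, 1886 and 256 for the interaction at 24 h, 48 h and over the mean. With a real count of 0 these splits test nothing. In the RCA at 12 h, where 5 genes were called, at least 12 of 100 splits gave over 3 times as many, up to 1746, and for the interaction at 12 h, with 1 gene called, at least 4 did, up to 336. Why these other splits gave more genes than the real one was not tested.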
